A study of Mus musculus x Mus spretus with 8 samples.

How the data were processed

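RNA was extracted with Trizol, and 1 microgram went into a TruSeq RNA preparation sequenced on an Illumina GAIIx. Whether poly-A selection was used is not given in the sources used here. Per the submitters' processing notes, HISAT2 2.0.5, Cufflinks, featureCounts and the mouse build mm10 were used, without a role or order for each. The values deposited by the authors are raw counts per Ensembl gene, with 3 measures for each of the 8 libraries: all assigned reads, reads assigned to genome 1 and reads assigned to genome 2. Whole numbers with unequal sums between libraries were found in every column, as raw counts require. The annotation version, the strand setting, the treatment of reads that map to several places and the tool that split reads by genome were not given in the sources used here. Without the strand setting, genes that overlap another gene are named as uncertain, and so are near copies such as the Saa genes. An aligner run against a reference of mm10 can favour C57BL/6 reads, so shares were compared between libraries and not read as absolute.

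The table held 49670 genes, of which 49411 matched GENCODE M21 on GRCm38 for symbols and coordinates; the 259 others held at most 0.014% of a library's counts. Total counts ran from 73128996 to 81500061 per library, 50.64 to 52.64% of them carried a genome, and mitochondrial genes took 4.64 to 8.18%. The median chi-square per gene within a pair was 2.81 in WT, 23.97 for Stc1, 9.5 for Pygo1 and 1.58 for Rlim, against 0.455 from counting alone, so counting error weighed most in the WT and Rlim-labelled pairs. Groups were taken from the labels: WT and the lines labelled Stc1, Pygo1 and Rlim, with 2 libraries each. The design, the alternatives, 37 gene lists and the rule for named genes were set before the data were examined.

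Gene counts were fitted in edgeR 4.0.16 (R 4.3.3) with TMM scaling and the default expression filter, which kept 17839 genes. A quasi-likelihood model with 1 mean per group was fitted over all 8 libraries, so that all groups share the estimate of spread (common biological coefficient of variation 24.6%, 2.94 prior degrees of freedom). Each knockout label was tested against WT and against the other labels, and genes at a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are fitted with edgeR and carry their standard errors. CPM values use the TMM factors. Gene lists and the chromosome sets were tested with limma 3.58.1 camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, which asks whether a list moves one way without comparing it with other genes. Lists needed at least 3 measured members. Adjusted values over a list alone used the p-values of its members only.

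Named genes were the targets and Xist; for each label against WT the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 CPM over the 4 libraries and both knockout libraries on the same side of both WT libraries; up to 4 members with the smallest adjusted p of each list with a called member; up to 4 X-linked genes in each direction; the 10 genes with the largest smallest change over the 3 labels; and 5 in each direction between knockout labels. Predicted genes without a symbol of their own were passed over. Kdm5c and Kdm6a, the genes given for their genome share and those that differed in opposite directions between labels were chosen after their values were seen.

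Allele counts were fitted in edgeR with a term for each library and a genome term for each group, and the difference of the genome term from WT was tested. In 329 genes the sum of both genomes exceeded all counts, and these were left out. Silenced X-linked genes were those with at least 20 reads of either genome in every library and a genome 1 share under 5% over all libraries. Log2 changes of allele counts used 1 added read and the TMM library sizes. A region was said to lack a genome where the median share over the 5 nearest genes on each side that use both genomes in WT (20 to 80%) lay under 10%, and a gene was said to use mainly 1 genome in WT from a share of 90%. Medians per chromosome are over genes with at least 50 such reads in every library. Intervals of shares are 95% Wilson intervals.

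The model was tested on simulated data with 200 changed genes, and allele counts with a 4-fold change of odds in 200 of 6406 genes, of which 100% were recovered with 2.91% false calls. Unchanged groups were simulated against the same WT libraries in 20 draws. The alternatives were other scalings, filters, tools, thresholds and samples in the fit, an added replicate term, and each library left out in turn. Scaling each chromosome to WT, leaving out libraries for the allele shares and counting windows nearly without a genome were added after the data were seen. All columns of the count table were used, and figures were drawn with matplotlib 3.10.9.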

Results

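RNA was sequenced in 8 libraries of Patski cells, a fibroblast line derived from a female hybrid mouse with a C57BL/6 and a SPRET/EiJ (Mus spretus) parent. In such a hybrid, reads that span a base at which the parents differ can be assigned to a parental genome, so the RNA of each chromosome of a pair is measured apart. The libraries formed 4 groups of 2: wild type (WT), and lines labelled as homozygous null for Stc1, Pygo1 or Rlim. Stc1 encodes stanniocalcin 1, a secreted glycoprotein of calcium and phosphate handling, and Pygo1 encodes a nuclear cofactor of beta-catenin in Wnt signalling. Rlim encodes an X-linked E3 ubiquitin ligase that promotes expression of Xist, the noncoding RNA that coats and silences an X chromosome. The total counts were 76125575 and 81500061 in WT, and 73128996 and 74961476 in the libraries labelled Stc1. They were 79145436 and 74346218 in those labelled Pygo1, and 74485191 and 76560193 in those labelled Rlim. Of all counts, 50.64 to 52.64% carried a genome. The labels do not say which parent is genome 1. Per the series description the knockout pairs are separate mutants, whereas nothing is said of how the WT pair was made, so the p-values measure only the spread between libraries.

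The targeted genes were measured first. Stc1 (chromosome 14, 69029238 to 69041804, GRCm38) stood at 3.67 and 68.4 CPM (counts scaled to equal library sizes) in the Stc1-labelled libraries against 3.84 and 3.14 in WT. Pygo1 (chromosome 9, 72925645 to 72952181) stood at 2.5 and 0.674 CPM in the Pygo1-labelled libraries against 2.49 and 2.44 in WT, and Rlim (chromosome X, 103957163 to 103981284) at 71.9 and 64.2 CPM in the Rlim-labelled libraries against 57.2 and 51.4. In no comparison was the RNA of the targeted gene lower past the test. The log2 fold changes were 3.37 ± 1.15 (SE) for Stc1, -0.63 ± 0.84 for Pygo1 and 0.33 ± 0.37 for Rlim (n = 2 per group; edgeR quasi-likelihood test, adjusted p = 0.236, 0.715 and 0.699). Stc1 was higher in Stc1-labelled replicate 2 by itself, at 19.6 times the WT mean. Its log2 fold change was 4.28 without Stc1-labelled replicate 1 and 0.065 without replicate 2, each resting on 1 library of the label. The Pygo1 value became 0.02 without Pygo1-labelled replicate 2. It was -1.87 without Pygo1-labelled replicate 1, as Pygo1 stood at 0.274 times the WT mean in replicate 2. With each chromosome scaled to WT, Rlim under its own label had a log2 fold change of 0.935 (edgeR, adjusted p = 0.0309), and with the Rlim-labelled and WT libraries alone 0.32 (edgeR, adjusted p = 1.87e-05). Counts per gene do not show whether a transcript carries a disrupting edit, so each group is named here by its label, and every direction given for a knockout label is a direction for a pair whose target RNA was not called lower.

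Xist (chromosome X, 103460366 to 103483254) stood at 783 and 758 CPM in WT. It was measured at 850 and 440 CPM in the Stc1-labelled libraries, at 390 and 351 in the Pygo1-labelled ones, and at 631 and 613 in the Rlim-labelled ones. The log2 fold changes were -0.26 ± 0.28, -1.06 ± 0.28 and -0.31 ± 0.28 (SE, n = 2 per group), and none passed the edgeR test (adjusted p = 0.692, 0.103 and 0.611). The Pygo1 value passed without Stc1-labelled replicate 1 (edgeR, adjusted p = 0.000792), without Stc1-labelled replicate 2 (0.000815), without a filter (0.0302), with the compared groups alone (0.00764) and by DESeq2 (adjusted p = 0.00761). The Rlim value passed without Stc1-labelled replicate 1 or 2 (edgeR, adjusted p = 0.0485 and 0.0479) and with the compared groups alone (2.56e-07). The Stc1 value was -0.82 without Stc1-labelled replicate 1 and 0.135 without replicate 2, each resting on 1 library of the label. Scaling each chromosome to WT turned the Stc1 and Rlim values to 0.28 and 0.30 and brought the Pygo1 value to -0.48. Between 99.12 and 99.68% of the Xist reads with a genome came from genome 1 in every library.

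**Figure D1:**
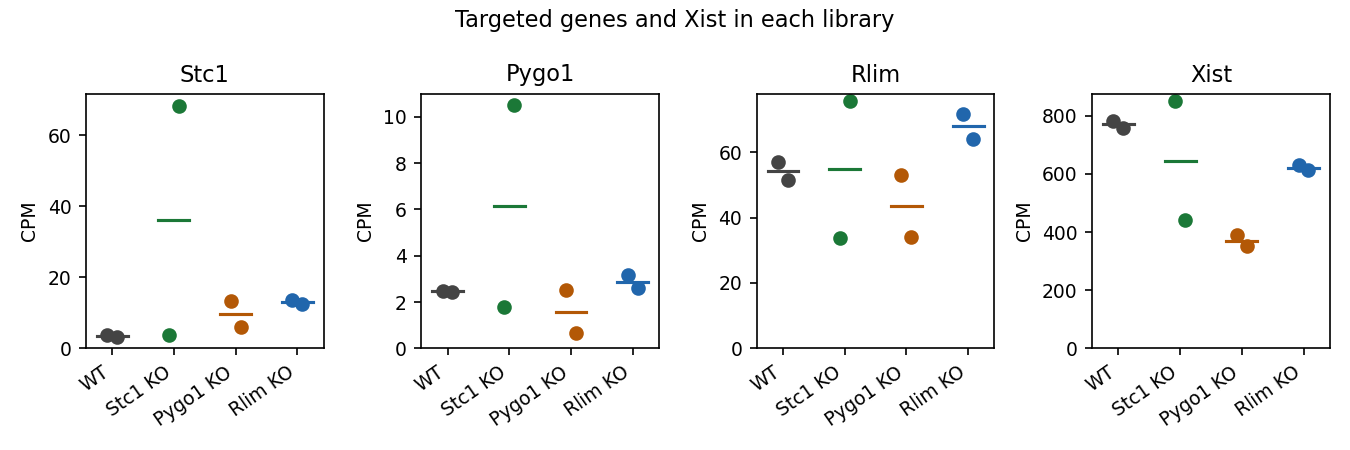
CPM (y axis) of Stc1, Pygo1, Rlim and Xist in each library by group (x axis), with points for libraries and lines for the mean of the 2. Stc1 stands at 68.4 CPM in Stc1-labelled replicate 2 and at 3.67 in replicate 1, and Xist lies below both WT libraries in each Pygo1-labelled library.

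The pairs of libraries differed in how closely they matched. The median absolute log2 difference within a pair was 0.10 in WT, 0.35 in the Stc1-labelled pair, 0.19 in the Pygo1-labelled pair and 0.06 in the Rlim-labelled pair. Of 10445 genes, 4, 1070, 257 and 2 differed over 2-fold within these pairs. The typical log2 distance within the Rlim-labelled pair was 0.101, against 0.135 in WT and 0.455 in the Pygo1-labelled pair. The values do not settle whether the Rlim-labelled libraries are separate lines or the same line sequenced again, in which case each Rlim value would rest on 1 line. A single spread was estimated for each gene over all 8 libraries, so the loose Stc1-labelled pair widened the error of every comparison. In simulated data with this spread, the edgeR test recovered 28, 26 and 26% of 2-fold changes and 83, 84 and 82% of 4-fold changes in the Stc1, Pygo1 and Rlim comparisons, with 5.13, 9.09 and 4.42% false calls. Every simulated library had the same spread for a gene, unlike the real pairs. These rates therefore do not describe the loose Stc1-labelled or the close Rlim-labelled pair.

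In the libraries labelled Stc1, Nos2 and Steap4 rose most and Sirpa fell most among the genes chosen for the size of their change. Nos2, the inducible nitric oxide synthase, rose from 5.13 and 4.99 CPM to 122 and 338 (45.4-fold). Steap4, a metalloreductase, rose from 0.716 and 0.777 to 19 and 23.8 CPM (28.6-fold; edgeR, adjusted p = 0.0161 for both). The neutrophil chemokine genes Cxcl1 and Cxcl5 rose 13.8-fold and 11.4-fold (log2 3.79 ± 0.27 and 3.51 ± 0.28, SE; edgeR, adjusted p = 0.00397 and 0.00738). Serpine2, a secreted protease inhibitor, Tnfrsf9, the costimulatory receptor 4-1BB, and Zc3h12a, a ribonuclease that degrades cytokine messages, rose 12.6-fold, 8.44-fold and 5.17-fold. Ltbp2, of the latent TGF-beta binding protein family, rose 10.3-fold, though it overlaps an antisense gene and the strand setting of the counting was not given. Neurl3 and Zfp521 rose 5.33-fold and 5.2-fold. Downward, Sirpa, the receptor of CD47, fell from 13.6 and 13.9 CPM to 0.111 and 0.12 (118-fold, log2 -6.88 ± 0.19; edgeR, adjusted p = 5.68e-05). Fxyd2, the gamma subunit of the kidney Na,K-ATPase, fell 9.17-fold from 73.2 and 79.6 CPM to 8.47 and 8.18 (edgeR, adjusted p = 0.000561). Cldn2, the X-linked claudin of leaky tubular epithelium, fell 5.44-fold from 133 and 132 CPM to 26.1 and 22.5 (edgeR, adjusted p = 0.00114). Wfdc2, Inmt and Olfm1 fell 26.1-fold, 16-fold and 11.6-fold. The genes of the oxytocin receptor (Oxtr), cystathionine gamma-lyase (Cth), aminopeptidase N (Anpep) and the sulfotransferase Chst1 fell 6.81-fold, 5.8-fold, 4.67-fold and 4.29-fold (edgeR, adjusted p between 0.00738 and 0.0445 for these genes). Over 17839 genes tested, 51 rose and 52 fell at an adjusted p under 0.05, of which 44 and 42 changed at least 2-fold. The count of 103 was 4 without WT replicate 1, 3 without WT replicate 2, 4484 without Stc1-labelled replicate 1, 1211 without Stc1-labelled replicate 2 and 14 without either Rlim-labelled replicate. With the Stc1-labelled and WT libraries alone no gene passed in edgeR (0, with 1735 at an unadjusted p under 0.05), and DESeq2 called 835. Of the 41 genes named for this comparison that passed, Sirpa, Fxyd2 and Cldn2 passed without WT replicate 1 (edgeR, adjusted p = 0.00233, 0.0248 and 0.0362) and without WT replicate 2 (0.00238, 0.0326 and 0.0349). Of the 41, 11 passed without either Rlim-labelled replicate, among them Cxcl1, Cxcl5, Lcn2 and Zc3h12a.

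Of the gene lists fixed beforehand, inflammatory cytokines and NF-kB targets moved most in the Stc1-labelled libraries. Of its 28 measured members 6 rose over all genes and 21 when adjusted over the list alone, with a median log2 fold change of 2.05 (limma camera, adjusted p = 9.2e-39; adjusted p = 0.101 with an estimated correlation). Ccl20, a chemokine for CCR6, rose 14.2-fold and Lcn2, the siderophore-binding lipocalin, rose 4.32-fold from 61.5 and 62.1 CPM to 265 and 269 (edgeR, adjusted p = 0.00397 for both). TGF-beta and BMP response genes rose as a group (median 0.46): 3 of 30 rose over all genes, and 12 rose and 1 fell when adjusted over the list alone (limma camera, adjusted p = 2.67e-08; adjusted p = 0.139 with an estimated correlation). Smad9 rose 3.57-fold and Id2 1.91-fold. Wnt/beta-catenin targets rose too (median 0.46), with 2 of 24 up over all genes and 6 adjusted over the list alone (limma camera, adjusted p = 0.00013; adjusted p = 0.172 with an estimated correlation). The called members include Fosl1, which overlaps another gene. Without Stc1-labelled replicate 2 the camera adjusted p of this list was 0.055. Glycolysis and hypoxia genes rose as a group (median 0.50): 1 of 35 rose and 1 fell over all genes, and 12 rose and 1 fell adjusted over the list alone (limma camera, adjusted p = 1.89e-07; adjusted p = 0.534 with an estimated correlation). Pfkl, a phosphofructokinase, rose 2.94-fold and the aldolase gene Aldoc fell 6.99-fold. Ccl20 and Lcn2 passed without either Rlim-labelled replicate and the other members named here did not, and none of them passed without WT replicate 1 or WT replicate 2, where 4 and 3 genes of all those tested passed.

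Other lists fell in the Stc1-labelled libraries. Cholesterol biosynthesis fell (median -0.49), with 1 of 24 down over all genes and 6 adjusted over the list alone (limma camera, adjusted p = 3.71e-09; adjusted p = 0.328 with an estimated correlation). The member called over all genes was Insig1, the retention factor of sterol regulatory proteins, at 1.99-fold, and its call ended without either Pygo1-labelled replicate. Unfolded protein response and amino acid stress genes fell (median -0.30), with 2 of 32 down over all genes and 9 adjusted over the list alone (limma camera, adjusted p = 6.8e-08; adjusted p = 0.101 with an estimated correlation). The ATF4 targets Trib3 and Chac1 fell 2.27-fold and 3-fold. NRF2 and antioxidant genes (median -0.40) and oxidative phosphorylation (median -0.23) also fell by limma camera (adjusted p = 0.00439 and 0.000728; adjusted p = 0.393 and 0.804 with an estimated correlation). No member passed in either direction in edgeR, over all genes or adjusted over the list alone. The NRF2 call ended without Stc1-labelled replicate 1 (limma camera, adjusted p = 0.126) and that of oxidative phosphorylation without Stc1-labelled replicate 2 (0.518). The X inactivation machinery (37 genes, median 0.06) and the X inactivation screen factors (10 genes) did not pass (limma camera, adjusted p = 0.254 and 0.249). Of the 37 lists 8 passed limma camera, the rest lay between 0.0582 and 0.989 in adjusted p, and 0 passed with an estimated correlation, where 5 had an unadjusted p under 0.05. By fry 4 lists passed, 3 of them also called by camera. All single members named here lost their edgeR call without WT replicate 1 or WT replicate 2, where 4 and 3 genes of all those tested passed.

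In the libraries labelled Pygo1, serum amyloid A genes rose most among the genes named, and those that fell most included Sirpa and Fxyd2 again. Saa3, an acute-phase serum amyloid A gene, rose 67.6-fold, from 3.01 and 3.11 CPM to 307 and 107 (edgeR, adjusted p = 0.0178). Its relatives Saa1 and Saa2 rose 332-fold and 118-fold, although reads of these similar copies may be split between them. Steap4 rose 60.7-fold to 65.9 and 24.8 CPM (log2 5.92 ± 0.51, SE; edgeR, adjusted p = 0.00578), and Nos2 rose 53.3-fold to 348 and 191 CPM (5.74 ± 0.57; edgeR, adjusted p = 0.00984). Phyh, a peroxisomal hydroxylase of phytanic acid, rose 26.4-fold, and Pde1b, a cyclic nucleotide phosphodiesterase, 24.5-fold (edgeR, adjusted p = 0.0161 and 0.00117). Krt17, Ltbp2 and Serpine2 rose 22.3-fold, 19-fold and 17.6-fold. Downward, Gstm4, a glutathione transferase, fell from 15.4 and 16.7 CPM to 0.126 and 0.0826 (151-fold, log2 -7.24 ± 0.34; edgeR, adjusted p = 0.000499). Sirpa fell 137-fold and Fxyd2 fell 108-fold to 0.705 and 0.702 CPM (edgeR, adjusted p = 2.54e-05 and 2.4e-05). Crtac1, Zfhx4, Wfdc2, Cnnm1 and Tmem178 fell between 4.24-fold and 68.5-fold, Cxcl12, the ligand of CXCR4, fell 12.8-fold, and Ucp2, a mitochondrial carrier, fell 4.71-fold (edgeR, adjusted p between 0.00239 and 0.0496). In all, 275 genes rose and 144 fell, of which 227 and 97 changed at least 2-fold. The count of 419 was 8 without WT replicate 1, 10 without WT replicate 2, 3680 without either Stc1-labelled replicate, 201 without Pygo1-labelled replicate 2 and 45 without either Rlim-labelled replicate. Of the 70 genes named for this comparison that passed, Pde1b, Ltbp2, Gstm4, Sirpa, Fxyd2 and Lcn2 passed without WT replicate 1 (edgeR, adjusted p between 0.00105 and 0.0408) and without WT replicate 2 (0.00107 to 0.0322). Of them 42 and 34 passed without Pygo1-labelled replicate 1 and 2, and 20 passed without either Rlim-labelled replicate.

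Inflammatory cytokines and NF-kB targets also led the lists in the Pygo1-labelled libraries. Of its 28 members 12 rose and 1 fell over all genes, and 20 rose and 1 fell adjusted over the list alone, with a median log2 fold change of 2.07 (limma camera, adjusted p = 1.47e-33; adjusted p = 0.185 with an estimated correlation). Lcn2 rose 16.6-fold to 1140 and 913 CPM, Cxcl1 14.2-fold, Cxcl5 11.5-fold and Ccl20 11.2-fold (edgeR, adjusted p between 0.000181 and 0.00415). Interferon response genes rose (median 0.73), with 2 of 44 up over all genes and 3 adjusted over the list alone (limma camera, adjusted p = 0.000535; adjusted p = 0.311 with an estimated correlation). The called members were the DNA sensor family gene Ifi204 (5.29-fold) and Trim30a (8.45-fold). Fibrillar collagens and matrix rose (median 0.98), with 1 of 33 up over all genes, and 9 up and 2 down adjusted over the list alone (limma camera, adjusted p = 0.000798; adjusted p = 0.311 with an estimated correlation). The matrix glycoprotein gene Fn1, which overlaps an antisense gene, rose 1.83-fold from 2230 and 2340 CPM to 3810 and 4560. Contractile and myofibroblast genes rose (median 0.58), with 2 of 24 up over all genes, and 8 up and 1 down adjusted over the list alone (limma camera, adjusted p = 0.000141; adjusted p = 0.311 with an estimated correlation). Lmod1, a smooth-muscle leiomodin gene, rose 17-fold and Synpo2 rose 3.01-fold. The camera adjusted p of this list was 0.0531 without Pygo1-labelled replicate 2. TGF-beta and BMP response genes rose (median 0.33), with 3 of 30 up over all genes, and 10 up and 2 down adjusted over the list alone (limma camera, adjusted p = 1.07e-05; adjusted p = 0.266 with an estimated correlation). Smad9 rose 2.94-fold and Id1 1.84-fold. Lcn2 passed in edgeR without either WT replicate and the other members named here did not; Lcn2, Cxcl1, Cxcl5, Ccl20 and Lmod1 passed without either Rlim-labelled replicate.

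Wnt/beta-catenin targets, the list closest to the known role of Pygo1, rose in the Pygo1-labelled libraries (median 0.37; limma camera, adjusted p = 0.00392; adjusted p = 0.287 with an estimated correlation). Over all genes 3 of 24 rose, and adjusted over the list alone 4 rose and 1 fell. Without Pygo1-labelled replicate 2 the camera adjusted p was 0.0615. The called members were Fosl1 (2.87-fold), Notum, which removes the lipid of Wnt proteins (6.63-fold), and Ascl2 (9.21-fold, at under 0.35 CPM in each library). Glycolysis and hypoxia genes rose (median 0.45), with 2 of 35 up over all genes and 10 adjusted over the list alone (limma camera, adjusted p = 2.66e-07; adjusted p = 0.311 with an estimated correlation). Those called over all genes were Pfkl (2.64-fold) and P4ha1 (2.09-fold). Cholesterol biosynthesis fell (median -0.54), with 6 of 24 down over all genes and 14 adjusted over the list alone (limma camera, adjusted p = 5.24e-11; adjusted p = 0.287 with an estimated correlation). Insig1 fell 2.74-fold, the sterol synthesis genes Nsdhl and Fdft1 fell 2.34-fold and 1.99-fold and Cyp51 fell 2.39-fold (edgeR, adjusted p between 0.00984 and 0.0256). Fdft1 and Cyp51 overlap other genes. Unfolded protein response and amino acid stress genes fell (median -0.33), with 6 of 32 down over all genes, and 7 down and 1 up adjusted over the list alone (limma camera, adjusted p = 6.52e-05; adjusted p = 0.185 with an estimated correlation). Chac1, Mthfd2 and Asns, enzymes of glutathione, folate and asparagine metabolism, fell 3.27-fold, 3.45-fold and 3.72-fold. Ribosomal proteins (median -0.29) and oxidative phosphorylation (median -0.18) fell by limma camera (adjusted p = 6.13e-05 and 0.00683; adjusted p = 0.545 and 0.641 with an estimated correlation) without a called member. The latter call ended without WT replicate 2 (0.0588) and without Pygo1-labelled replicate 1 (0.0731). None of the members named here passed in edgeR without WT replicate 1 or 2, where 8 and 10 genes of all those tested passed, and Fosl1 alone of them passed without either Rlim-labelled replicate.

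Histone genes and lists of cell identity also shifted in the Pygo1-labelled libraries. Histone genes (median 0.90), endothelial (0.50), macrophage and leukocyte (0.66), adipocyte (0.49) and fibroblast identity markers (0.48) rose by limma camera (adjusted p = 0.00355, 0.0187, 0.016, 0.016 and 0.0382; adjusted p = 0.397, 0.294, 0.287, 0.473 and 0.294 with an estimated correlation). At most 1 member of each passed over all genes: Cd68, a lysosomal protein of macrophages, rose 3.36-fold from 1.81 and 2.39 CPM to 7.61 and 6.52. When adjusted over the list alone, 2 macrophage, 2 endothelial and 3 adipocyte markers rose and 2 adipocyte markers fell. The histone call ended without Pygo1-labelled replicate 2 (limma camera, adjusted p = 0.157). The adipocyte call ended without WT replicate 2 (0.0846) and without Pygo1-labelled replicate 2 (0.271). The fibroblast call ended without any 1 library except WT replicate 2 (camera adjusted p = 0.0756 without WT replicate 1, 0.0833 and 0.0815 without Stc1-labelled replicates 1 and 2, 0.136 and 0.124 without Pygo1-labelled replicates 1 and 2, 0.0896 and 0.0881 without Rlim-labelled replicates 1 and 2). Hox genes fell (median -0.24), with 1 of 31 down over all genes and 3 adjusted over the list alone (limma camera, adjusted p = 0.013; adjusted p = 0.436 with an estimated correlation; adjusted p = 0.144 without Pygo1-labelled replicate 1). Among kidney epithelium markers, Aqp1, the water channel, fell 3.51-fold from 5050 and 5470 CPM to 1540 and 1450, and the E-cadherin gene Cdh1 fell 33.7-fold from 9.52 and 8.91 to 0.201 and 0.344 CPM (edgeR, adjusted p = 0.0161 for both). Gata3 of the same kidney list rose 2.97-fold from under 1 CPM (edgeR, adjusted p = 0.0383; 0.0867 and 0.0859 without Pygo1-labelled replicates 1 and 2). As groups neither list passed limma camera. The kidney list had a median of -0.26 (limma camera, adjusted p = 0.207; fry, adjusted p = 0.027), with 1 up and 2 down adjusted over the list alone. The epithelial list had a median of 0.37 (limma camera, adjusted p = 0.177), with 7 up and 2 down adjusted over the list alone. The X inactivation machinery (median -0.14) did not pass (limma camera, adjusted p = 0.245); its 1 called member, Ciz1, which overlaps another gene, rose 1.52-fold. Of the 37 lists 18 passed limma camera, the rest lay between 0.0668 and 0.994 in adjusted p, and 0 passed with an estimated correlation, where 6 had an unadjusted p under 0.05. By fry 11 lists passed, 9 of them also called by camera. Single members of these lists, Cd68, Aqp1, Gata3, Cdh1 and Ciz1 included, lost their edgeR call without WT replicate 1 or 2, where 8 and 10 genes of all those tested passed, and without either Rlim-labelled replicate, where 45 passed.

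In the libraries labelled Rlim, Steap4, Saa3 and Nos2 rose most among the genes chosen for the size of their change, and Gstk1 and Cxcl12 fell most. Steap4 rose 61.1-fold to 48.3 and 43.1 CPM (log2 5.93 ± 0.51, SE; edgeR, adjusted p = 0.00993), Saa3 42.9-fold (adjusted p = 0.0298) and Nos2 38.8-fold to 191 and 202 CPM (5.28 ± 0.56; adjusted p = 0.0182). Cxcl5 rose 20-fold and Lcn2 17.6-fold, to 1070 and 1100 CPM (edgeR, adjusted p = 0.00373 and 0.000241). Ltbp2, Tnfrsf9, Cxcl1, Neurl3 and Tbkbp1, an adaptor of the kinase TBK1, rose 15.9-fold, 12.7-fold, 12.6-fold, 10.1-fold and 6.05-fold. Downward, Gstk1, a glutathione transferase on chromosome 6, fell from 18.8 and 20 CPM to 0.0786 and 0.0257 (363-fold, log2 -8.50 ± 1.05; edgeR, adjusted p = 0.0245). Also on chromosome 6, Cxcl12 fell 124-fold, Rassf4 33.4-fold from 38.6 CPM in both WT libraries to 1.19 and 1.12, and Gpnmb, a transmembrane glycoprotein of lysosomes, 6.65-fold from 244 and 248 CPM to 38.4 and 35.6 (edgeR, adjusted p = 0.0129, 0.02 and 0.0424). Fxyd2 fell 18.6-fold, Cldn2 5.74-fold, Wfdc2 25.8-fold, and Slc6a18, an amino acid transporter of the proximal tubule, 12.6-fold from 99.8 and 102 CPM to 7.42 and 8.59 (edgeR, adjusted p between 0.000236 and 0.0386). Cth and Oxtr fell 3.8-fold and 3.34-fold. In all, 140 genes rose and 110 fell, of which 108 and 78 changed at least 2-fold. The count of 250 was 3 without WT replicate 1, 3 without WT replicate 2, 3035 and 3034 without Stc1-labelled replicate 1 and 2, and 7 and 9 without Rlim-labelled replicate 1 and 2. It was 8340 when the Rlim-labelled and WT libraries were fitted alone, since both of these pairs matched closely. Of the 55 genes named for this comparison that passed, Lcn2, Fxyd2 and Cldn2 passed without WT replicate 1 (edgeR, adjusted p = 0.0304, 0.0121 and 0.0304) and without WT replicate 2 (0.0293, 0.015 and 0.0293). Cxcl5, Lcn2, Ltbp2, Neurl3, Fxyd2, Cldn2 and Cebpd passed without either Rlim-labelled replicate.

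The lists moved in the Rlim-labelled libraries as follows. Inflammatory cytokines and NF-kB targets rose (median 1.40), with 7 of 28 up and 1 down over all genes, and 20 up and 1 down adjusted over the list alone (limma camera, adjusted p = 2.76e-31; adjusted p = 0.183 with an estimated correlation). TGF-beta and BMP response genes rose (median 0.33), with 4 of 30 up over all genes, and 10 up and 1 down adjusted over the list alone (limma camera, adjusted p = 1.17e-06; adjusted p = 0.183 with an estimated correlation). Id1, Id2 and Smad9 rose 2.7-fold, 1.88-fold and 3.49-fold. Contractile and myofibroblast genes rose (median 0.31), with Lmod1 called over all genes at 5.71-fold, and 3 up and 1 down adjusted over the list alone (limma camera, adjusted p = 0.00572; adjusted p = 0.518 with an estimated correlation). Glycolysis and hypoxia genes rose (median 0.30), with Pfkl up 2.85-fold and Aldoc down 3.68-fold over all genes, and 5 up and 2 down adjusted over the list alone (limma camera, adjusted p = 0.00168; adjusted p = 0.673 with an estimated correlation). Endothelial markers rose (median 0.54), with Pecam1 called at 23.4-fold (limma camera, adjusted p = 0.0432; adjusted p = 0.421 with an estimated correlation). This call ended without WT replicate 1 (0.0689), either Stc1-labelled replicate (0.0552 and 0.0557), either Pygo1-labelled replicate (0.0951 and 0.106) or Rlim-labelled replicate 2 (0.055). Wnt/beta-catenin targets did not pass (limma camera, adjusted p = 0.108), although 4 of 24 rose over all genes, and 5 rose and 1 fell adjusted over the list alone, with Notum at 9.1-fold. Without WT replicate 1 or 2, where 3 genes of all those tested passed, no single member of these lists except Lcn2 kept its edgeR call.

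Cholesterol biosynthesis fell in the Rlim-labelled libraries (median -0.65), with 3 of 24 down over all genes and 16 adjusted over the list alone (limma camera, adjusted p = 1.65e-15; adjusted p = 0.183 with an estimated correlation). Nsdhl fell 2.59-fold, Fdft1 2.03-fold and Insig1 1.87-fold. Cytosolic ribosomal proteins fell (median -0.55), with none of 39 down over all genes and 27 adjusted over the list alone (limma camera, adjusted p = 1.49e-17; adjusted p = 0.421 with an estimated correlation). Unfolded protein response and amino acid stress genes fell (median -0.30), with Chac1 down 2.19-fold over all genes and 4 down adjusted over the list alone (limma camera, adjusted p = 0.000951; adjusted p = 0.183 with an estimated correlation). NRF2 and antioxidant genes (median -0.31, with 1 member down adjusted over the list alone) and oxidative phosphorylation (median -0.23) fell by limma camera (adjusted p = 0.0387 for both; adjusted p = 0.433 and 0.708 with an estimated correlation). These calls ended without WT replicate 2 (camera adjusted p = 0.0733 and 0.191) and, for oxidative phosphorylation, without Rlim-labelled replicate 2 (0.0532). The RLIM substrates and LIM-domain partners (17 genes, median 0.18) and the X inactivation machinery did not pass (limma camera, adjusted p = 0.0598 and 0.644), with 3 substrates up adjusted over the list alone. By fry of limma the RLIM substrates passed upward (adjusted p = 0.0278). Of the 37 lists 11 passed, the rest lay between 0.0598 and 0.999 in adjusted p, and 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05. By fry 7 lists passed, 5 of them also called by camera. Of the kidney epithelium and epithelial markers, Aqp1 fell 2.64-fold to 1930 and 2060 CPM and Cdh1 18.2-fold to 0.498 and 0.514 (edgeR, adjusted p = 0.0386 and 0.0298), while Gata3 rose 3.16-fold (edgeR, adjusted p = 0.0386; 0.0532 and 0.0525 without Pygo1-labelled replicates 1 and 2). As groups neither list passed. The kidney list had 3 up and 2 down adjusted over the list alone (median -0.23; limma camera, adjusted p = 0.499). The epithelial list had 4 up and 1 down (median 0.57; limma camera, adjusted p = 0.0887). Single members named here lost their edgeR call without WT replicate 1 or 2, where 3 genes of all those tested passed, and without Rlim-labelled replicate 1 or 2, where 7 and 9 passed.

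**Figure D2:**
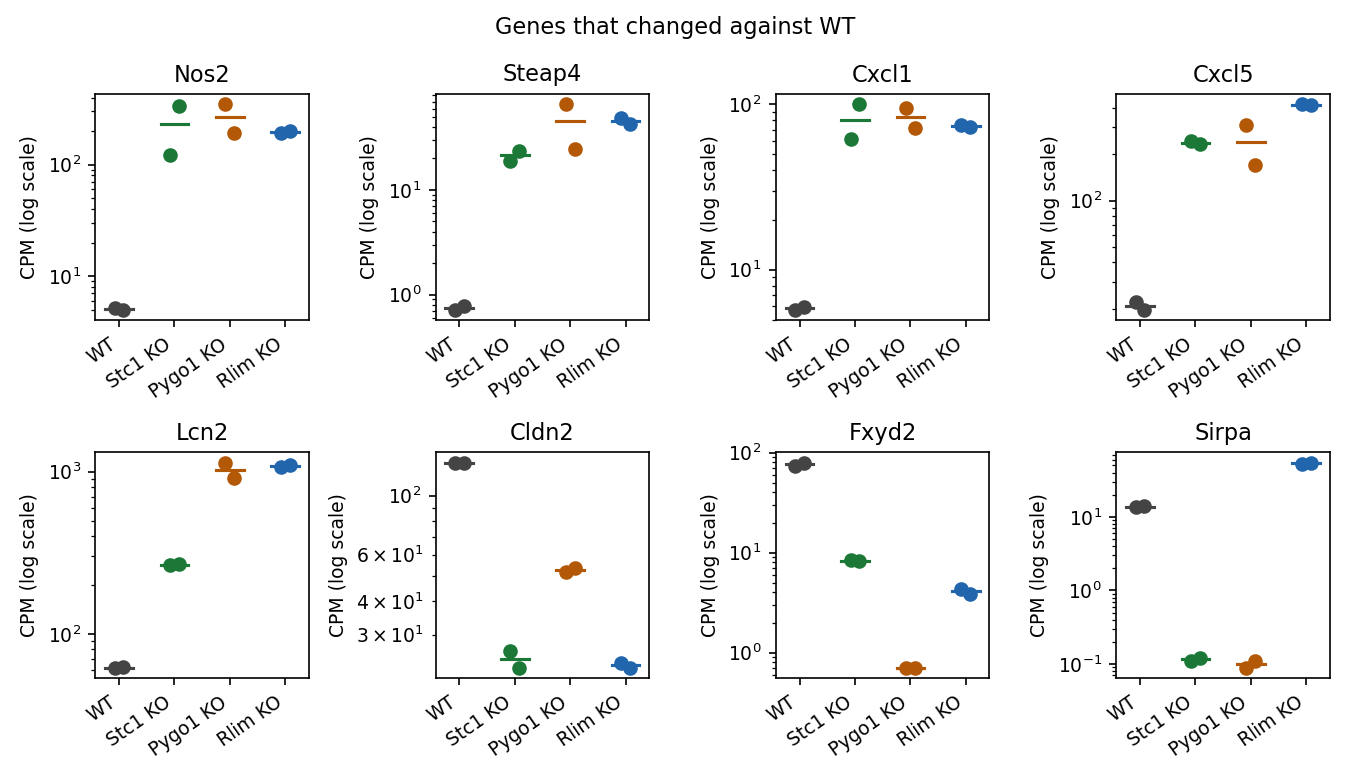
CPM on a log axis (y) of Nos2, Steap4, Cxcl1, Cxcl5, Lcn2, Cldn2, Fxyd2 and Sirpa in each library by group (x), with points for libraries. Lcn2 goes from 61.5 and 62.1 CPM in WT to 1140 and 913 in the Pygo1-labelled pair, and Sirpa stands above WT in the Rlim-labelled pair, at 52.2 and 54.8 CPM.

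Across the 3 knockout labels, 31 genes rose and 16 fell in every comparison with WT. Those up in all 3 included Steap4, Nos2, Cxcl1, Cxcl5, Ccl20, Lcn2 and Ltbp2, and Vtcn1, an inhibitory ligand of T cells, up 16.4-fold, 15.5-fold and 18.6-fold. Those down included the transport genes Fxyd2 and Cldn2, the secreted protein gene Wfdc2 and the X-linked gene Bex1. Independent lists of these sizes would share 0.0062 genes up and 0.0026 down, and unchanged groups simulated against the same WT libraries shared 0.05 on average and at most 1 over 20 draws. Between pairs of labels, 40 genes rose and 25 fell in both Stc1 and Pygo1 (0.786 and 0.42 if independent), 38 and 21 in both Stc1 and Rlim (0.4 and 0.321), and 69 and 46 in both Pygo1 and Rlim (2.16 and 0.888), while 1, 3 and 6 went opposite ways. The covariance of the log2 fold changes across genes was 0.373, 0.362 and 0.416, against 0.111, 0.112 and 0.111 in the simulation, and the correlations were 0.494, 0.513 and 0.515 against 0.501, 0.502 and 0.498; genes are not independent replicates. The 2 WT libraries were not split between comparisons, so part of the excess may come from the shared controls. The count of 47 genes was 1 without WT replicate 1 or 2, 688 without Stc1-labelled replicate 1, 390 without Stc1-labelled replicate 2, and 6 and 8 without Rlim-labelled replicate 1 and 2.

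The knockout labels were also set against each other. Between the Stc1 and Pygo1 labels, Gstm4 and Car13, a cytosolic carbonic anhydrase, were 177-fold and 107-fold higher in the Stc1-labelled libraries (edgeR, adjusted p = 0.000744 for both), and Cdh1, Zfhx4 and Crtac1 were 48.5-fold, 44.2-fold and 27.1-fold higher. Phyh was 93.4-fold lower there, and Wscd1, Pla2g5, Fndc1 and the noncoding gene Lncenc1 were 49.1-fold to 141-fold lower (edgeR, adjusted p between 0.0107 and 0.0336). Against the Rlim label, the Stc1-labelled libraries held 310-fold more Gstk1 and 80.5-fold more Cxcl12, and Cdh1, the cadherin gene Cdh11 and Gpnmb were 26.1-fold, 24-fold and 11.1-fold higher (edgeR, adjusted p between 0.0271 and 0.0428). Sirpa and Stom, a membrane scaffold gene, both on chromosome 2, were 457-fold and 91.5-fold lower (edgeR, adjusted p = 1.43e-05 and 0.000775), as were Olfm1, Chst1 and Kng1, by 15.7-fold, 5.08-fold and 4.45-fold. Between the Pygo1 and Rlim labels, Phyh and Postn, a secreted matrix protein gene, were 18.8-fold and 15-fold higher in the Pygo1-labelled libraries, with Mlxipl, Adh7 and Pde1b 10.2-fold to 21.8-fold higher. Sirpa, Gstm4, Car13, Stom and Crtac1 were 533-fold, 173-fold, 111-fold, 65.8-fold and 50.3-fold lower (edgeR, adjusted p between 1.32e-05 and 0.0451). The counts were 91 genes up and 219 down for Stc1 against Pygo1, 20 and 48 for Stc1 against Rlim, and 104 and 78 for Pygo1 against Rlim. The totals of 310, 68 and 182 were 22, 4 and 21 without either WT replicate, 4087, 4844 and 2361 without Stc1-labelled replicate 1, 2372, 917 and 2359 without Stc1-labelled replicate 2. They were 166 and 94 for the first and the third without Pygo1-labelled replicate 2, and 25, 2 and 7 without either Rlim-labelled replicate. Of the 10 genes named in each, Gstm4 and Car13 passed in the first, Sirpa and Stom in the second, and Pde1b, Sirpa, Gstm4, Car13 and Stom in the third without WT replicate 1 or 2.

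The X chromosome was examined as a set because the counts were split by genome in a female line and Rlim acts on Xist. X-linked RNA was lower as a set under all 3 knockout labels: the median log2 fold change of 592 X-linked genes was -0.21 for Stc1, -0.47 for Pygo1 and -0.48 for Rlim, against 0.02, 0.01 and 0.02 for 17157 autosomal genes. Negative values made up 70.1, 79.4 and 78.9% of X-linked and 47.6, 49.1 and 48.4% of autosomal genes. The set passed limma camera with its preset correlation (adjusted p = 0.00053, 1.32e-09 and 4.03e-10) and lost the call otherwise. It had an adjusted p = 0.825, 0.96 and 0.829 with an estimated correlation, and 0.594, 0.35 and 0.362 by fry of limma. The fry test asks whether the genes move one way and does not compare them with others. The medians differed within pairs, at -0.76 and 0.03 in Stc1-labelled replicates 1 and 2, -0.28 and -0.84 in the Pygo1-labelled ones, and -0.58 and -0.64 in the Rlim-labelled ones. Without Stc1-labelled replicate 1 the Stc1 set reversed its direction (limma camera, adjusted p = 0.612), and without Pygo1-labelled replicate 2 the Pygo1 set passed at 0.00694.

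Few X-linked genes passed by themselves: 2 rose and 2 fell for Stc1, 3 and 10 for Pygo1, and 1 and 7 for Rlim. Tspan7, a tetraspanin gene, rose under all 3 labels (1.93-fold, 3.66-fold and 1.65-fold), Bex1 fell 58-fold, 39.7-fold and 14.1-fold from 5.65 and 6.29 CPM in WT, and Eda rose 11.8-fold under the Stc1 label (edgeR, adjusted p between 0.00124 and 0.046). Car5b, a mitochondrial carbonic anhydrase gene among those that escape X inactivation, fell 2.45-fold and 2.66-fold for Pygo1 and Rlim, Gspt2 fell 19.8-fold for Pygo1, and Amot and Shroom4 fell 2.08-fold and 1.63-fold for Rlim. Among X-linked genes the share called down was 1.69% for Pygo1 against 0.78% of autosomal genes (Fisher's exact test, two-sided, p = 0.03), 1.18 against 0.6% for Rlim (exact p = 0.0987) and 0.34 against 0.29% for Stc1 (exact p = 0.692). The escape gene list fell for Pygo1 (median -0.46; limma camera, adjusted p = 0.000798; adjusted p = 0.311 with an estimated correlation), with 1 of 17 down over all genes and 4 adjusted over the list alone. It fell for Rlim too (median -0.47; limma camera, adjusted p = 0.000935; adjusted p = 0.421 with an estimated correlation) with 2 and 3 down. With each chromosome scaled to WT these medians became 0.07 and 0.13. For Stc1 the list did not pass (median -0.25; limma camera, adjusted p = 0.0582). Of the genes named here, Tspan7, Gspt2 and Cldn2 were still called for Pygo1 without either Rlim-labelled replicate, and none but Cldn2 for Stc1 and Rlim was called without WT replicate 1 or 2, where between 3 and 10 genes of all those tested passed.

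Other chromosomes moved as sets too. Chromosome 6 was lower under all 3 labels (median log2 fold change -0.10, -0.26 and -0.32; limma camera, adjusted p = 0.0372, 9.24e-06 and 4.03e-10; adjusted p = 0.825, 0.96 and 0.437 with an estimated correlation). By library its median was -0.02 and -0.37 in the Stc1-labelled pair, -0.34 and -0.32 in the Pygo1-labelled pair, and -0.36 and -0.37 in the Rlim-labelled pair. Chromosome 14 was lower for Stc1 and Pygo1 (adjusted p = 1.7e-06 and 2.8e-06 by limma camera; adjusted p = 0.268 and 0.577 with an estimated correlation). The mitochondrial genes were lower for Stc1 (median -0.39; limma camera, adjusted p = 0.00372; adjusted p = 0.825 with an estimated correlation). By library the mitochondrial median was 0.07 and -0.75 in Stc1-labelled replicates 1 and 2, so the fall for Stc1 came from replicate 2. The median was -0.505 and -0.454 in the Pygo1-labelled pair, and -0.272 and -0.294 in the Rlim-labelled pair. The set did not pass for Pygo1 and Rlim (limma camera, adjusted p = 0.212 and 0.165). Chromosome 8 was higher for Stc1 (median 0.21; limma camera, adjusted p = 2.83e-05; adjusted p = 0.671 with an estimated correlation), with medians of 0.08 and 0.28 in replicates 1 and 2. Of 21 chromosome sets, limma camera called 5 up and 6 down for Stc1, 3 and 3 for Pygo1 and 5 and 3 for Rlim with its preset correlation, and 0 in each comparison with an estimated one, where 2, 1 and 2 had an unadjusted p under 0.05.

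**Figure D3:**
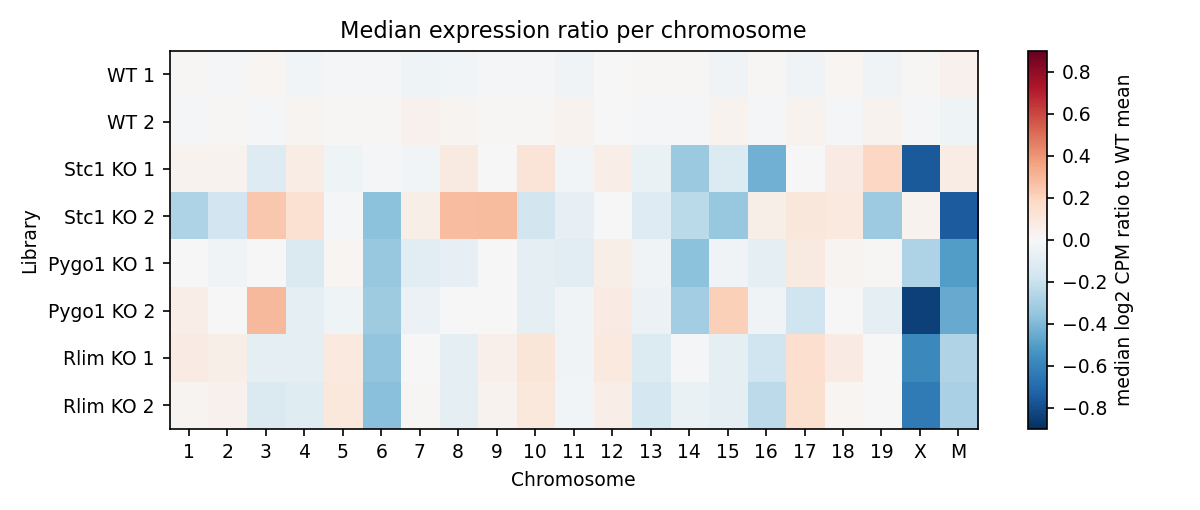
Median log2 ratio of CPM to the WT mean (colour) per chromosome (x axis) and library (y axis). The X chromosome stands at -0.76 and 0.03 in the Stc1-labelled pair and at -0.58 and -0.64 in the Rlim-labelled pair, and chromosome 6 stands between -0.32 and -0.37 in 5 of the 6 knockout libraries.

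Read by genome, nearly all X-linked RNA came from genome 2 in every library, while Xist came from genome 1. Leaving Xist out, genome 1 gave 5.16% ± 0.051 (SD, n = 2) of X-linked reads in WT, 5.38% ± 1.0 in the Stc1-labelled, 5.60% ± 0.67 in the Pygo1-labelled and 5.30% ± 0.034 in the Rlim-labelled pair. By library it was 5.12% (95% Wilson interval 5.071 to 5.17) and 5.192% in WT, 6.112 and 4.645% for Stc1, 5.132 and 6.077% for Pygo1, and 5.278 and 5.326% for Rlim; such intervals cover counting error only. The Stc1 and Pygo1 means differed from WT by less than the SD of their own pair, while both Rlim-labelled libraries lay above both WT libraries, by more than the SD of either pair. Genes called silenced, with a pooled genome 1 share under 5%, stood at 0.477, 0.488, 0.525 and 0.629% in the 4 groups. Their share was higher in both Rlim-labelled libraries (0.617 and 0.641%) than in both WT libraries (0.494 and 0.459%), and it was 0.62 and 0.43% in the Pygo1-labelled pair. Gene by gene, the edgeR test of the genome 1 share called 0 of 480 X-linked genes for Stc1 (15 at an unadjusted p under 0.05), 1 for Pygo1 and 2 for Rlim, with 7 and 16 unadjusted. Recovery of changes at such low shares was not simulated, so few calls do not show that the shares were unchanged. Mid1, whose gene spans the pseudoautosomal boundary in C57BL/6, had a higher genome 1 share under both labels (log2 odds 1.10 ± 0.25 and 1.28 ± 0.24; edgeR, adjusted p = 0.0365 and 0.0378). Its genome 1 share was 86.24 and 86.68% in WT, 91.91 and 94.37% for Pygo1, and 94.05 and 93.83% for Rlim. Tspan7 went from 0.48 and 0.2% to 1.52 and 1.56% for Rlim (log2 odds 2.14 ± 0.38; edgeR, adjusted p = 0.0396). These are shares of 417 and 495 reads in WT and of 725 and 705 for Rlim, so they rest on few genome 1 reads. Reads assigned to the wrong genome could weigh on them. These calls all ended without either WT or either Rlim-labelled replicate. For Stc1 the count was 2 without Stc1-labelled replicate 1 and 1 without Stc1-labelled replicate 2 or either Pygo1-labelled replicate. For Pygo1 it was 5 without either Stc1-labelled and 3 without either Pygo1-labelled replicate, and for Rlim 1 and 5.

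Genes known to escape X inactivation took 27.0% ± 0.76 (SD, n = 2) of their reads from genome 1 in WT, 26.8% ± 12 in the Stc1-labelled, 29.2% ± 5.5 in the Pygo1-labelled and 27.5% ± 0.28 in the Rlim-labelled pair. Kdm5c, a histone demethylase gene, stood at 33.1 and 33.3% in WT, 44.2 and 21.8% in the Stc1-labelled, 26.3 and 38.8% in the Pygo1-labelled and 34 and 32.6% in the Rlim-labelled libraries. Kdm6a, another demethylase gene, stood at 37.64 and 35.54%, 53.75 and 25.62%, 22.76 and 40.86%, and 39.38 and 40.76%. Shroom4 of the same list stood at 12.5 and 12.3% in WT and at 28.2 and 43.8% in the Pygo1-labelled libraries. For Stc1 it stood at 10.2 and 0.124%, and for Rlim at 13.6 and 12.5%. Ddx3x went the other way for Pygo1, from 24.2 and 26% in WT to 16.4 and 14%. Neither was among the genes whose share edgeR called. In the 2 libraries of the Stc1 label the X chromosomes moved in opposite ways. Genome 2 reads of 252 silenced genes had a median log2 change of -0.78 in replicate 1 and 0.03 in replicate 2, and genome 1 reads of 12 escape genes had medians of 0.06 and -0.73. In the Pygo1-labelled libraries the genome 2 median was -0.27 and -0.87 and the genome 1 median -0.67 and -0.68, and in the Rlim-labelled libraries they were -0.58 and -0.64, and -0.45 and -0.39.

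**Figure D4:**
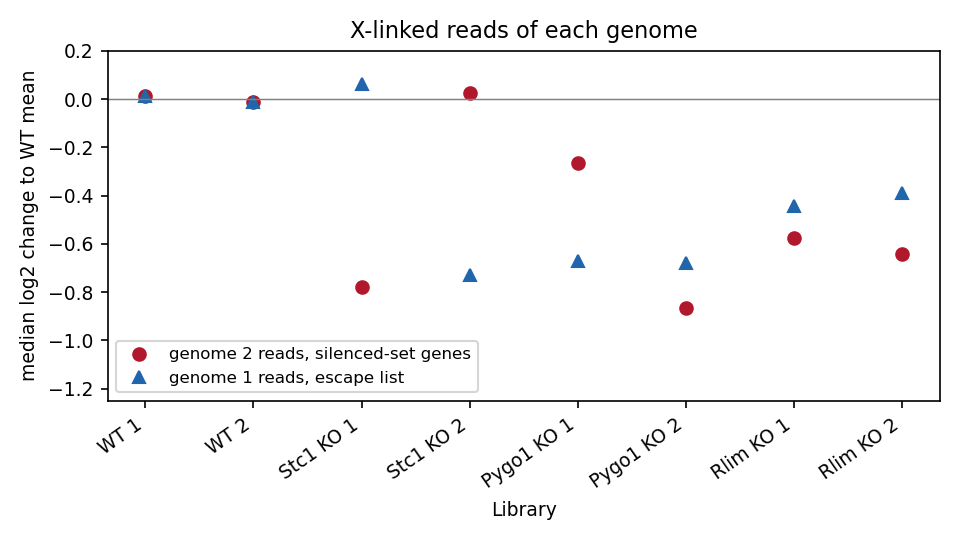
Median log2 change from the WT mean (y axis) in each library (x axis). Circles show genome 2 reads of 252 silenced X-linked genes, and triangles show genome 1 reads of 12 escape genes. Stc1-labelled replicate 1 lies at -0.78 and 0.06, and replicate 2 at 0.03 and -0.73.

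On the autosomes, whole chromosomes and parts of them used a different mix of genomes in the knockout lines than in WT. The edgeR test of the genome 1 share over 15097 autosomal genes called 124 genes toward genome 1 and 533 toward genome 2 for Stc1, 1427 and 909 for Pygo1, and 1094 and 210 for Rlim. Neighbouring genes share such a shift and are not independent. On chromosome 2, which holds Sirpa and Stom, the median genome 1 share was 6.82 and 6.93% in WT, 1.35 and 1.38% in the Stc1-labelled, 1.45 and 1.35% in the Pygo1-labelled, and 23.43 and 23.31% in the Rlim-labelled libraries. Sirpa took 90.6 and 88.1% of its WT reads and 93.6% of its Rlim-label reads from genome 1, and fell where chromosome 2 had little of that genome. On chromosome 9 the median genome 2 share was 1.35% in both WT libraries and between 0.08 and 0.14% in the 6 knockout libraries. Genome 2 reads were nearly missing over further regions: on chromosome 3 for Pygo1 (0.25 and 0.16%, against 20.7 and 20.76% in WT), and on chromosome 6 for Pygo1 (5.07 and 0.22%) and Rlim (0.28 and 0.22%, against 27.99 and 28.11%). Of 7273 autosomal genes read from both genomes in WT, 14.8 and 21% lay in such regions in the Pygo1-labelled libraries, 5.64 and 5.46% in the Rlim-labelled and 1.15 and 0.0412% in the Stc1-labelled ones. Genes of that choice cannot lie in such regions in WT, and they include 143 genes of chromosome 2, where most genes took few WT reads from genome 1. Over all 131 windows of 20 megabases with at least 10 genes, whatever their share in WT, the median genome 2 share was under 1% in 1 window in each WT library. It was so in 10 and 9 windows in the Stc1-labelled, 20 and 30 in the Pygo1-labelled and 15 and 14 in the Rlim-labelled libraries. The median genome 1 share was under 1% in 5 windows in each WT library, in 10 and 11, 11 and 10, and 8 and 7 in these pairs. The genome 2 counts of every knockout library include all windows of chromosome 9 and the chromosome 3 window ending at 140000000. WT medians of genome 1 were already at least 98% in the former, and 97.9 and 98.5% in the latter. So most windows counted for Stc1 held little genome 2 in WT too.

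**Figure D5:**
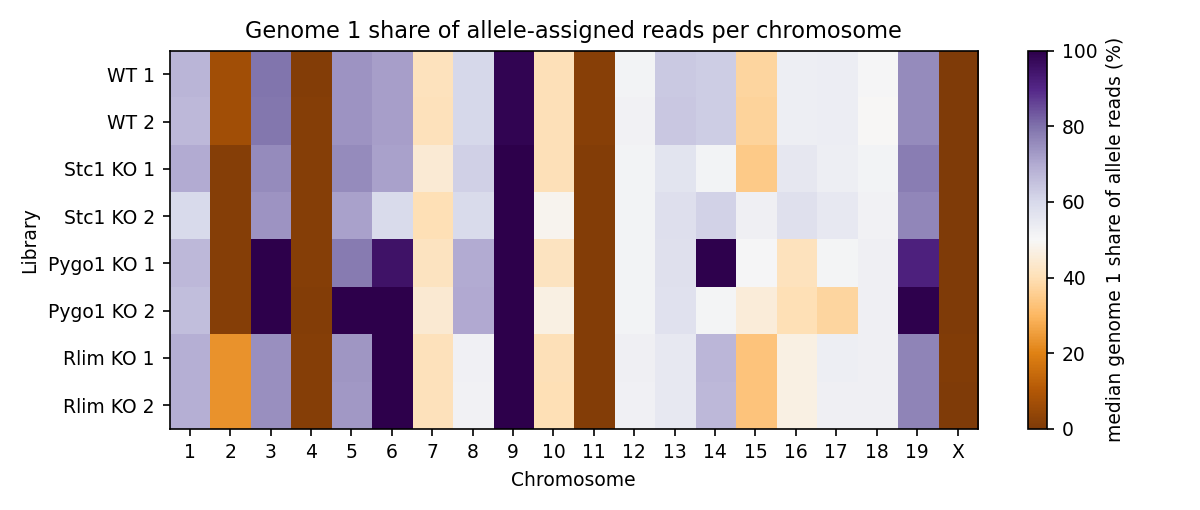
Median share of reads from genome 1 in percent (colour) per chromosome (x axis) and library (y axis). Chromosome 2 stands at 6.82 and 6.93% in WT and at 23.43 and 23.31% in the Rlim-labelled pair.

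RNA levels in regions that lacked genome 2 by the rule used, a local median share under 10%, were set against those elsewhere. Genome 2 reads could remain there: its median share on chromosome 6 was 5.07% in Pygo1-labelled replicate 1. For Rlim, 421 genes that used both genomes in WT lay in such regions, all on chromosome 6. Their median log2 fold change was -0.41, and 14 fell and 0 rose in edgeR. The 7249 genes elsewhere that used both genomes in WT had a median of 0.02, so for Rlim 1 chromosome was set against others. For Pygo1 these medians were -0.20 over 844 genes, of which 10 rose and 19 fell, and -0.01 over 5782 genes elsewhere. The Pygo1 value differed by chromosome, with medians of -0.39 on chromosome 6 (410 genes), -0.24 on chromosome 19 (136 genes) and 0.09 on chromosome 3 (298 genes). The chromosome 6 median was also -0.37 in Stc1-labelled replicate 2, where its genome 2 share was 40.56%. Where WT had used mainly the genome that the region lacked by this rule, the median was -0.57 for Rlim (15 genes, 3 down) and -0.35 for Pygo1 (35 genes, 2 down). The quartiles were -3.896 and -0.393 for Rlim, and -1.773 and 0.061 for Pygo1. Many of these genes are pseudogenes or predicted genes by name, and near copies are uncertain. Where the genome mainly used in WT was kept, the median was -0.071 for Rlim (67 genes, 0 up and 1 down). It was 0.241 for Pygo1 (158 genes, 6 up and 2 down). Among the genes whose main genome was lacking by this rule, Gpnmb took 2.1 and 1.75% of its reads from genome 1 in WT and 90.8 and 90% under the Rlim label. Rassf4 went from 5.09 and 5.47% to 90.9 and 93.3%. Under the Pygo1 label, where Gpnmb lay in such a region too, its genome 1 share was 76.1 and 93.1% and its RNA did not fall (log2 0.13; edgeR, adjusted p = 0.891). In Pygo1-labelled replicate 1, genome 2 still gave 4678 Gpnmb reads against 14906 from genome 1, so the loss was incomplete there. Aqp1 took 73.3 and 73.2% of its reads from genome 1 in WT and 99.8% in both Rlim-labelled libraries. Gstm4 on chromosome 3, read mostly from genome 2 in WT (genome 1 at 7.79 and 5.58%), fell under the Pygo1 label where genome 2 was nearly missing. Without WT replicate 1 or 2 the RNA level of Gstm4 still passed for Pygo1 (edgeR, adjusted p = 0.0124 and 0.0135), and those of Gpnmb and Rassf4 did not pass for Rlim, where 3 genes of all those tested did.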

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

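All tests of an explanation in this part were chosen after the results were seen. Genes that passed the edgeR test in opposite directions under different knockout labels, with a called difference between the labels, numbered 8, of which 4 lay on chromosome 2. Sirpa fell under the Stc1 and Pygo1 labels and rose under the Rlim label, so that the log2 difference was -8.84 between Stc1 and Rlim and -9.06 between Pygo1 and Rlim (edgeR, adjusted p = 1.43e-05 and 1.32e-05). Stom, whose protein organises membrane lipids, did likewise, with differences of -6.52 and -6.04 (edgeR, adjusted p = 0.000775 and 0.000538). Malrd1, also on chromosome 2, differed by -8.18 between Pygo1 and Rlim (edgeR, adjusted p = 0.0139), from 0.0252 and 0 CPM to 4.17 and 4.37. Tgm5, a transglutaminase gene on the same chromosome, had a fitted difference of -9.22 between Stc1 and Rlim (edgeR, adjusted p = 0.0225), a value that depends on the fit because both Stc1-labelled libraries were at 0 against 0.996 and 0.951 CPM. Gm5641 on chromosome 3 differed by -6.32 between Pygo1 and Rlim, and Gm7932 on chromosome 6 by 3.53 (edgeR, adjusted p = 0.00574 and 0.00508).

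Lgals9, which encodes the immune lectin galectin 9, stood at 26.3 and 28.8 CPM in WT, 14.6 and 15.5 under the Stc1 label and 79.6 and 80.4 under the Pygo1 label, a log2 difference of -2.41 (edgeR, adjusted p = 0.00088). Pdlim2, which encodes a PDZ-LIM protein that limits NF-kB signalling, stood at 12.4 and 14.8 CPM in WT, 24.1 and 24.2 under Pygo1 and 5.79 and 6.23 under Rlim, a log2 difference of 2 (edgeR, adjusted p = 0.00582). The allele counts also held a signal that the labels do not describe. Among autosomal genes chosen for using both genomes in WT, which sets WT to 0, the share in regions without genome 2 reads was 1.15 and 0.0412% in Stc1-labelled replicates 1 and 2, 14.8 and 21% in the Pygo1-labelled ones, and 5.64 and 5.46% in the Rlim-labelled ones.

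Reads of a second genome were seen in WT on chromosomes 2 and 9, where the knockout libraries had almost none or more. Chromosome 11 showed a smaller gap: its median genome 1 share was 1.62 and 1.77% in WT and 0.88 to 1.01% in the knockouts. Reads assigned to the wrong genome were argued against: the WT genome 2 share on chromosome 9 was 9.64 times the highest knockout share (1.35 against 0.14%), while on chromosome 4, read almost wholly from genome 2, the minor share, that of genome 1, was 1.1 and 1.26% in WT and 1.15 to 1.37% in the knockout libraries. A candidate explanation is a WT culture that mixes cells with different copies of chromosomes 2 and 9. On chromosome 2, 770 genes were kept for a genome 1 share well above that of the Stc1 and Pygo1 libraries in the Rlim libraries. Their WT share lay at a median of 21.6% of the way from the former to the latter (quartiles 18.4 and 28.4). Of these genes, 99.5% lay between the ends. The RNA levels of Sirpa and Stom gave 25.6 and 23.7%. Sirpa and Stom were picked for opposite calls, and the WT median of chromosome 2 already lay between those of the labels. A place between the ends was thus given beforehand. These values do not separate mixed cells from an intermediate output in every cell. Uneven copies within every WT cell were argued against, since the share of 1.35% on chromosome 9 would need 73.1 copies of a homologue to 1 of the other, while weak output of a copy kept in every cell stays open, as single cells or clones were not analysed here.

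Lower X-linked RNA was the second pattern weighed. Scaling between libraries was argued against, since the X-linked median lay below the autosomal one by log2 -0.48 or more in the Pygo1 and Rlim comparisons. In the Stc1-labelled pair an unequal dose or output of the 2 X chromosomes may account for it: genome 1 reads of escape genes and genome 2 reads of silenced genes moved apart by at least 0.76 in both senses (0.84 in replicate 1, -0.76 in replicate 2). In the Pygo1-labelled and Rlim-labelled libraries both fell and their differences were smaller (-0.41 and 0.19, 0.13 and 0.25), so unequal output and a fall of both X chromosomes cannot be told apart there. Loss of the targeted genes, the biological explanation that the design names, cannot be told apart from line-to-line differences, because libraries of the same label differed by up to 0.79 in the X-linked median for Stc1 and by 0.56 for Pygo1 but by 0.06 for Rlim.

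The shared rise of inflammatory RNA was the third. Under all 3 labels 31 genes rose, against at most 1 gene in simulated groups without any change set against shared WT libraries. Such groups give few calls, and a state common to both WT libraries was not simulated. The count thus goes beyond noise alone but does not exclude the shared WT libraries as a source. Leukocytes in the knockout cultures were argued against as the source of the Lcn2 rise: the 9 leukocyte markers under 5 CPM in WT rose together by at most 0.95% of the rise of Lcn2 (from 6.71 CPM in WT to 8.39, 15.9 and 10, while Lcn2 rose by 205, 962 and 1030 CPM), and Ptprc stood at 0.0376 to 0.288 CPM in all libraries. Lcn2 reached means of 1020 and 1090 CPM under the Pygo1 and Rlim labels, so this ratio does not cover genes with smaller rises. The full list of 11 measured leukocyte markers passed upward for Pygo1 (limma camera, adjusted p = 0.016, and 0.287 with an estimated correlation). What stays open is the derivation or culture of the lines or the state of the WT pair, since the lowest median log2 ratio of the list in a knockout library was 1.1 and no other unedited culture was analysed here. An effect common to the lost genes cannot be told apart from these, for the same reason.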

How the results depend on the processing

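Most fold changes kept their direction, while calls depended on the spread estimate. Of 208 values for named genes, 207 kept direction and side of the threshold with DESeq2 (1 passed in addition), 206 with RLE scaling, 202 with library size alone, 186 with limma voom, 206 without a filter, 145 with the compared groups alone, 89 with the replicate block (119 no longer passed), and 180 with each chromosome scaled to WT, an alternative chosen after seeing the data; with each library left out in turn, 907 of 1664 values were the same, 741 no longer passed, 11 passed in addition and 5 changed sign. The effect of depth was not tested by thinning reads.

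Counts of called genes are given in the order Stc1, Pygo1 and Rlim against WT, then Stc1 against Pygo1, Stc1 against Rlim, Pygo1 against Rlim, and genes shared by all 3; in edgeR they were 103, 419, 250, 310, 68, 182 and 47. Without a filter they were 361, 867, 610, 683, 333, 519 and 126, and with DESeq2 835, 1564, 1248, 1184, 776, 1015 and 225; the cause was not tested. With the compared groups alone they were 0, 1699, 8340, 0, 12, 972 and 0, with 1735 and 1260 genes at an unadjusted p under 0.05 for the first and the fourth; by construction each pair then sets its own spread. At an adjusted p of 0.01 they were 14, 49, 15, 23, 5, 20 and 9, by construction fewer. A filter at 5 CPM moved 3 of them, to 270 (Pygo1 against WT), 36 (Stc1 against Rlim) and 91 (Pygo1 against Rlim). RLE scaling, library size alone, limma voom and chromosome scaling kept each within 1.5 times. The share of calls that rose for Pygo1 was 347 of 490 with chromosome scaling. With each library left out, the counts ranged from 3 to 4484, 8 to 3680, 3 to 3035, 22 to 4087, 2 to 4844, 7 to 2361 and 1 to 688. The lowest came without a WT or Rlim-labelled library and the highest without Stc1-labelled replicate 1, because the spread is shared and the lone sample left in a group is assumed to vary like the others.

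The labels give the groups the same replicate numbers and do not say whether these pair the libraries. Over 10445 genes, the correlation of replicate differences was 0.376 between WT and Rlim, 0.174 between WT and Pygo1 and 0.165 between Pygo1 and Rlim. With Stc1 it was 0.01 for WT, -0.203 for Pygo1 and -0.007 for Rlim. A replicate effect shared by the WT, Pygo1 and Rlim groups therefore stays open, and the main fit leaves it out. With the replicate block the counts were 18, 109, 26, 96, 7, 38 and 11, and the block ended the Adipocyte call for Pygo1 (limma camera, adjusted p = 0.0505) and the endothelial call for Rlim (0.121); it added the escape gene call for Stc1 (0.0401) and left the X-linked set called.

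X-linked genes as a set lost their call with an estimated correlation (limma camera, adjusted p = 0.825, 0.96 and 0.829) and by fry (0.594, 0.35 and 0.362); the cause was not tested. For Stc1 the adjusted p ranged from 1.8e-12 to 0.612 with each library left out, and reversed without Stc1-labelled replicate 1. Without Xist and the escape genes it was 0.000731, 2.64e-09 and 8.54e-10. With an estimated correlation, 0 gene lists and 0 chromosome sets passed limma camera in each comparison, against 8, 18 and 11 lists and 11, 6 and 8 chromosome sets with the preset; 5, 6 and 4 lists and 2, 1 and 2 chromosome sets had an unadjusted p under 0.05. With each library left out, 269 of 296 list calls held.

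Signs of uncalled targets turned in these cases, and the cause was not tested. Under the Stc1 label, Rlim had a log2 fold change of -0.012 without a filter and -0.093 with limma voom, and ranged from -0.68 to 0.48 with each library left out; Pygo1 ranged from -0.47 to 2.09, and Xist from -0.82 to 0.14 and stood at 0.28 with chromosome scaling. Pygo1 under its own label ranged from -1.874 to 0.018. With chromosome scaling, Rlim under the Pygo1 label was 0.21 and Xist under the Rlim label 0.30. X-linked genes with a changed genome share ranged from 0 to 2, 0 to 5 and 0 to 5 with each library left out. With at least 20 reads in every library, the genome 1 share of X-linked reads was 5.08% in WT and 5.23% under the Rlim label, against 5.16 and 5.3%, more than the spread within these close pairs.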

Other observations

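All tests of an explanation were chosen after the results were seen, and this part gives values without one. The label of the line is fibroblast, and its RNA held high levels of kidney tubule genes. Pax2 and Pax8, transcription factors of the developing kidney, stood at 649 to 1160 and 455 to 622 CPM over the 8 libraries, and Cdh16, the kidney-specific cadherin, at 1220 to 2360 CPM. Aqp1 stood at 1450 to 5470 CPM. The mesenchymal filament gene Vim stood at 832 to 1280 CPM, whereas Col1a1, the main fibroblast collagen gene, stood at 2.03 to 8.19 CPM and the keratin gene Krt8 at 0.213 to 1.68 CPM. The leukocyte genes Ptprc and Lyz2 did not exceed 0.288 and 0.275 CPM.

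Within the knockout pairs, Stc1-labelled replicate 2 stood apart from every other library. Its typical log2 distance to the other 7 was 0.684 to 0.805, against 0.469 and 0.475 between Stc1-labelled replicate 1 and the WT libraries, 0.135 within WT and 0.101 within the Rlim-labelled pair. This library held the highest Stc1 (68.4 CPM), Pygo1 (10.5 CPM) and Rlim (75.8 CPM) levels of all 8, and mitochondrial genes took 4.64% of its counts against 6.12 to 8.18% elsewhere. In the first 40 megabases of chromosome 1, Stc1-labelled replicate 1 took 99.6 and 98.9% of its reads from genome 1 in successive windows of 20 megabases, against 72.5 and 71.7% in WT replicate 1. On chromosome 5 Pygo1-labelled replicate 2 had a genome 2 share of 0.17%, and on chromosome 14 Pygo1-labelled replicate 1 had one of 0.76%.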
